A study of Mus musculus with 4 samples.

How the data were processed

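Single cells of whole prostates of C57BL6 mice were profiled with the 10x Genomics method in 4 libraries, 2 labelled control and 2 labelled HFD, read as a high-fat diet from the series description. The labels give a tissue digestion with collagenase in a medium with dihydrotestosterone; they give neither the composition nor the length of the diet. Each library's title has its own number after the letter M, read as a mouse number; the labels do not state that each library is 1 animal. Per the labels, the authors made UMI counts per gene and cell barcode with Cell Ranger 3.1.0 on the mouse genome mm10 with an Ensembl 92 annotation; the same labels also name a human build, and the deposited gene identifiers are mouse identifiers. The other deposited tables hold the cell barcodes and the gene names in the order of the counts. Seurat 3.5.1 is named among the submitters' processing tools, per the labels, and the deposited counts are whole numbers without scaling. How barcodes were called as cells is not given in the sources used here. Gene positions were taken from the GENCODE annotation of mm10.

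The 4 libraries held 6700, 4887, 5000 and 8364 barcodes and 84544193, 34197642, 45726313 and 76332452 UMIs in control 1, control 2, HFD 1 and HFD 2. Their median UMIs per barcode were 3103, 2873, 6854 and 3362.5, and the smallest 500, 501, 2891 and 500. HFD 1 held exactly 5000 barcodes and had a higher minimum than the other libraries; how its barcodes were selected is not given. Intervals for shares are exact Clopper-Pearson 95% intervals and cover counting error only, and a count of 0 is given with the share that 3 counts would make, or for Glycam1 with the upper end of its interval.

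Barcodes with at least 300 detected genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept, which left 5103, 4350, 4962 and 5967. Doublet scores came from Scrublet, run per library in scanpy 1.11.5 with an expected rate of 0.06. Its automatic threshold marked 3 cells in all, so the cells with the highest scores were removed instead, at 0.8% per 1000 cells, a choice made after seeing this. This removed 208, 151, 197 and 285 cells and left 4895, 4199, 4765 and 5682, with 6017, 3275, 6886 and 4928 median UMIs.

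The 19541 cells were clustered on 2000 variable genes chosen within libraries, 30 principal components, 15 nearest neighbours with shared-neighbour weights and the Leiden method (leidenalg 0.10.2) at a resolution of 1, with a random seed of 7 and no batch correction. Clusters were named from fixed marker lists. A named cluster had at least 3 markers of a class at a log2 level of 1 or more over the median cluster and in at least 10% of its cells, with at least 2 of them among its 50 leading genes. A cluster stayed unnamed when over 90% of its cells came from 1 library, when at least 2 of its 10 leading genes were those of another kind of cell, or when it was shallow with no marker among the 10. These thresholds were set after seeing the data. Of 43 clusters, 25 were named into 14 classes with 14699 cells and 18 stayed unnamed: 9 were nearly all from 1 library, 6 were led by other genes and 3 had too few markers. Class names mean that the cells carry the markers of a type, not that the type was established. The clusters left unnamed for their leading genes held 21.4%, 6.22%, 5.94% and 5.32% of the cells of control 1, control 2, HFD 1 and HFD 2.

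UMI counts were summed per class and library, so that libraries and not cells were the replicates. The main classes had at least 50 cells in every library, up to 5 classes. The 6 other classes with at least 20 cells in every library were planned as counts of genes only. Genes past the threshold are named for smooth muscle-like cells in addition to that plan. Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM normalisation, filterByExpr) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. SE is the absolute log2 fold change over the square root of F. For 25 fixed gene lists, limma 3.58.1 camera compared a list's genes with all other tested genes, with a preset correlation of 0.01 and adjustment over 120 combinations of list and class; a list needed 5 tested members. The alternatives were an estimated correlation and fry, whose p-value says whether a list's genes move on balance one way, and whose mixed p-value whether they change in either direction; neither compares the list with other genes. Numbers of cells per class were tested with edgeR with the library's cell number as its size, and by an exact permutation test of the shares. The difference of the HFD effect between classes was tested as an interaction with the library as a block. Dividing cells were counted from Mki67, Top2a, Cdk1, Ccnb1, Birc5 and Ube2c.

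The comparisons, tests, gene lists, marker lists, the other settings to be tried and the rule for naming genes were fixed before the data were examined. The rule names, per class, the 10 called genes with the largest rise and the 10 with the largest fall at a mean log2 CPM of at least 4 and with groups that do not overlap. Where fewer than 5 genes passed it names the 5 with the smallest p, and for each list past its threshold the 4 members with the smallest p, of which some are given in the text. Predicted genes and genes of ribosomal and mitochondrial proteins were passed over in the first part. The genes called by DESeq2 in small numbers, and the immunoglobulin, chemokine and Glycam1 genes of the closing part, were chosen after their values were seen. Irf7 and Cxcl5 were chosen for a picture and for their positions after their values were seen. For free RNA, each gene's level in a class is given as a percentage of that in the class where it is highest.

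Alternatives were DESeq2 1.42.0, median-ratio (RLE) size factors, no low-count filter, each library left out in turn, doublets kept, a mitochondrial limit of 10%, a minimum of 500 genes, naming each cell by its highest marker score (at least 0.25), genes under 10% of their highest class left out, equal cell numbers per class, TMM over classes, shares within epithelial or non-epithelial cells, a Leiden resolution of 0.5 or 2, and no thinning or 1 UMI for dividing cells. A common UMI minimum, tests per epithelial cluster, list tests of the interaction and leaving out libraries for the interaction and for dividing cells were added after the data were seen. The edgeR and camera steps were tested on simulated data drawn from the libraries' own means: changes of 2 log2 units were recovered for 100% of changed genes in secretory luminal-like and seminal vesicle epithelial-like, 99% in basal-like, 96% in proximal luminal-like and 44% in fibroblast-like cells, and changes of 1 log2 unit for 39%, 38%, 36%, 33% and 3.19%, with 3, 9, 4, 8 and 1 false calls in this order. The changed genes had a mean log2 CPM of at least 4, and every gene had the spread typical for its level. Genes that vary more between libraries were thus not simulated. Each gene was drawn independently of the others, so the simulation cannot tell whether camera's preset correlation suits these data. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. Glial-like, T or NK cell-like and B or plasma cell-like cells were too few in a library for a test of genes and were compared by share only.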

Results

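The mouse prostate holds secretory, basal and proximal luminal epithelium in a stroma of fibroblasts and smooth muscle, with blood vessels and immune cells between them. The comparison asked how a high-fat diet (HFD) altered the make-up of this tissue and the gene expression of its cells. Lymphocyte-like cells made up a smaller share of the HFD libraries than of the control libraries, and the difference for B or plasma cell-like cells passed its test. No other class passed. Values after ± are standard errors (SE) for log2 fold changes of HFD over control and standard deviations (SD) for group means, with n = 2 libraries per group throughout. The titles give each library its own number after the letter M, read as a mouse number, but do not state that each library is 1 animal, so the p-values measure the spread between these samples. All tests were two-sided.

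B cells carry surface immunoglobulin and plasma cells secrete it. B or plasma cell-like cells were 51 of 4895 cells in control 1 (1.04%, exact Clopper-Pearson 95% interval 0.777 to 1.37%) and 208 of 4199 in control 2 (4.95%, 4.32 to 5.65%). In the HFD libraries they were 3 of 4765 cells in HFD 1 (0.063%, 0.013 to 0.184%) and 10 of 5682 in HFD 2 (0.176%, 0.0844 to 0.323%). The group means were 3.0% ± 2.76 and 0.119% ± 0.0799, and the share fell with a log2 fold change of −4.60 ± 1.28 (edgeR adjusted p = 0.0176 over 15 groups of cells). The merged class hides a difference that was seen afterwards and not tested. Its cells with a UMI of the plasma cell gene Jchain were 1 and 12 in control and 3 and 7 in HFD libraries, which overlapped. Those with the naive B cell gene Ighd were 27 and 91 against 0 and 2. The fall was thus not seen in the cells with Jchain. T or NK cell-like cells, the classes of cell-mediated immunity, were 3.49% and 10.7% of the control libraries and 0.105% and 1.78% of the HFD libraries, with a log2 fold change of −2.91 ± 1.16 that did not pass (edgeR adjusted p = 0.132). An exact permutation test of 2 against 2 libraries cannot go below p = 0.333, which was its value for both classes. The smallest barcode of HFD 1 held 2891 UMIs and those of the other libraries 500 or 501; with 2891 UMIs as the minimum everywhere, a choice made after seeing the data, the log2 fold changes were −3.84 ± 0.95 for B or plasma cell-like and −3.44 ± 0.87 for T or NK cell-like cells (edgeR adjusted p = 0.00329 for each). The B or plasma cell-like call ended without control 2 (−3.09, edgeR adjusted p = 0.634), without HFD 1 (−4.07, 0.477), without HFD 2 (−5.51, 0.238) and as a share of the non-epithelial cells (−3.25, 0.0941), and its adjusted p lay between 0.00268 and 0.634 over all alternatives.

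**Figure D1:**
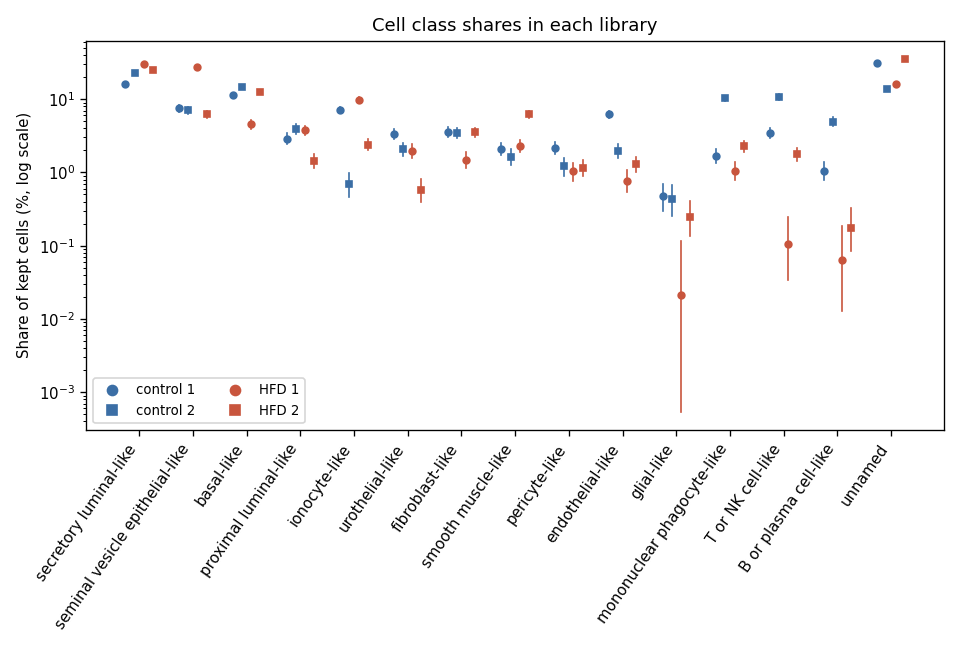
Share of each named class among the kept cells of each library, in percent on a log scale, with exact Clopper-Pearson 95% intervals as bars; blue marks control and red marks HFD libraries. B or plasma cell-like cells sit at 1.04% and 4.95% in the control libraries and at 0.063% and 0.176% in the HFD libraries.

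Secretory luminal-like cells, which make the bulk of prostatic fluid, were 16.1% and 23% of the control and 29.9% and 25.4% of the HFD libraries, which did not overlap, with means of 19.6% ± 4.88 and 27.6% ± 3.18 (log2 fold change 0.50 ± 1.08, edgeR adjusted p = 0.749). With 2891 UMIs as the minimum everywhere the groups overlapped, at 24.2% and 34.3% of the control and 29.9% and 33.8% of the HFD libraries. The log2 fold change was then 0.12 ± 0.76. These shares leave out unnamed clusters in which secretory luminal markers ranked first, so the class's full share stays unsettled. Cluster 21 held 351 cells of HFD 1, and clusters 26, 29 and 30 held 242, 205 and 188 of HFD 2. Each had at most 7 cells of a control library. Cluster 5, led by neuronal genes, held 752 and 130 control cells against 19 and 28 HFD cells. Cluster 19 held 164 and 63 against 6 and 195. Basal-like cells were 13.1% ± 2.33 and 8.52% ± 5.64, and smooth muscle-like cells 1.87% ± 0.325 and 4.25% ± 2.77. Seminal vesicle epithelial-like cells were 7.29% ± 0.269 of control and 16.7% ± 14.8 of HFD cells, since they made up 27.2% of HFD 1 and 6.2% of HFD 2; this tissue adjoins the prostate. Svs2, Svs4 and Svs5, which encode seminal vesicle secretions, together took 14.0% and 10.3% of the UMIs of the control libraries and 27.2% and 13.0% of those of HFD 1 and HFD 2. Endothelial-like cells were 6.21% and 1.95% of the control libraries and 0.776% and 1.3% of the HFD libraries (edgeR adjusted p = 0.407). Mononuclear phagocyte-like cells were 6.0% ± 6.08 and 1.67% ± 0.877, and cluster 18 held 68.9% of them in control while cluster 25 held 56.1% in HFD libraries. Of the control cells of cluster 18, 21 were in control 1 and 333 in control 2. Ionocyte-like cells, named for their proton pump genes, were mostly cluster 16 in control (77.0%) and cluster 12 in HFD libraries (70.9%). Cells left without a name were 22.4% ± 12.1 of control and 25.5% ± 13.3 of HFD cells. Of the 14 epithelial clusters, 0 passed the same edgeR test on shares and 0 had an unadjusted p below 0.05; the smallest adjusted p was 0.664.

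Proximal luminal-like cells lie near the urethra and hold stem-like epithelium. In these cells the chemokine gene Cxcl5 fell, and it was the gene that passed the test among 9349. Cxcl5 (ENSMUSG00000029371.7; mm10 chromosome 5, 90759360 to 90761624, plus strand) encodes a chemokine that draws neutrophils. Its TMM-normalised CPM (UMI counts scaled to the library's effective total) were 59.3 and 72.4 in the control libraries and 8.05 and 5.81 in the HFD libraries, a log2 fold change of −3.24 ± 0.36 (edgeR adjusted p = 0.0425). By DESeq2, 2 genes passed, Cxcl5 (−3.29, adjusted p = 8.15e-05) and Svs4 (1.80, adjusted p = 0.00605). By edgeR, 186 genes had an unadjusted p below 0.05, fewer than chance alone would give among the 9349 tested. The same held for this count in every other main class, so these counts by themselves are no sign of changed genes. Without 1 library, edgeR called between 10 genes (control 2 left out) and 35 genes (HFD 2 left out). The Cxcl5 call ended with doublets kept (−2.41, edgeR adjusted p = 0.431), with cells named by marker score (−2.55, 0.283) and with equal cell numbers per library (−1.73, 1.0), and the adjusted p lay between 1.35e-11 and 1.0 over all alternatives.

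Interferon response genes were lower with HFD in the same cells. Of the 15 tested members, which are switched on by viral and other danger signals, 12 were lower and the median log2 fold change was −0.71 (limma camera adjusted p = 1.42e-11; 0.70 with an estimated correlation). Without control 2 the median was −0.05 (camera adjusted p = 0.0425). Adjusted over the list alone, 4 members were lower: Ifi27l2a (−3.58 ± 0.72), Irf7 (−1.53 ± 0.31), Ifi44 (−3.08 ± 0.82) and Ifit3 (−2.10 ± 0.61). Of these, Ifi27l2a, Ifi44 and Ifit3 stood at 4.06 to 5.93% of their level in the class where each was highest, and Irf7 at 42%. The other lists of these cells that passed were lost with an estimated correlation as well (adjusted p = 0.70 to 0.757). Cholesterol synthesis genes fell (median −0.52, camera adjusted p = 3.11e-05), with Fdps at −1.03 ± 0.42 but at 0.64 with cells named by marker score, and so did ribosomal protein genes (−0.27, 0.000167). Unfolded protein response genes rose (0.32, 0.00579), with Herpud1 at 0.79 ± 0.33 and a median of 0.02 without HFD 1, as did insulin and IGF signalling genes (0.31, 0.0488), with Irs1 at 1.02 ± 0.53. Adjusted over the list alone, 0 members of these 4 lists passed. Genes of prostate secretory proteins rose as a list (0.77, 9.51e-07) and 2 passed when adjusted over the list alone, Msmb (3.27 ± 0.77) and Defb50 (2.94 ± 0.83), at 1.87 and 2.84% of their highest class. HFD 1 carried both: without it their log2 fold changes were 1.02 and 0.37. Androgen response genes (0.09, 0.00354) followed with Msmb and Steap4 (1.47 ± 0.39) adjusted over the list alone, and mitochondrially encoded RNA rose (0.25, 0.0357). The smooth muscle genes Mylk (2.92 ± 0.45) and Tagln (4.38 ± 0.82) and the secretory gene Spinkl (1.45 ± 0.29) had small p values, at 0.146 to 0.522% of their highest class, and did not pass (edgeR adjusted p = 0.382 for Mylk and 0.795 for the others).

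Secretory luminal-like cells make the proteins of prostatic fluid under androgen control. Interferon response and MHC class I genes fell as lists in these cells, while inflammation, cholesterol synthesis and matrix genes rose; all were lost with an estimated correlation (camera adjusted p = 0.70 for each). No single gene passed: of 14914 genes, edgeR called 0 and gave 285 an unadjusted p below 0.05, fewer than chance alone would give. DESeq2 called 12, 11 of them higher. The genes with the smallest p above the expression floor were the potassium channel gene Kcnk3 (1.32 ± 0.26), Ceacam10 (1.01 ± 0.22), Mapre2 (0.85 ± 0.19), Pgap1 (0.95 ± 0.21) and Lysmd1 (−0.90 ± 0.20), with an edgeR adjusted p of 1.0 each; Ceacam10 stood at 0.927% of its highest class. Without 1 library, edgeR called between 1 gene (control 1 left out) and 17 genes (control 2 left out).

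Of 25 lists in secretory luminal-like cells, 15 passed the camera test, 9 higher and 6 lower; with an estimated correlation 0 passed. The cells were spread differently over their clusters in the 2 groups: cluster 3 held 29.4% of them in control and 16.0% in HFD libraries, cluster 7 8.96% and 15.3%, and cluster 11 8.56% and 13.8%. HFD 1 carried the rises of clusters 7 and 11, with 358 and 290 of its 1425 cells. HFD 2 had 81 and 107 of 1443 cells there. Tested singly, clusters 2, 3, 4, 7 and 11 had 0 genes past the edgeR test, with 110 to 178 at an unadjusted p below 0.05. Interferon response genes had the lowest median (−1.16, camera adjusted p = 5.98e-15; adjusted p = 0.70 with an estimated correlation), with 16 of 17 members lower, 5 of them lower in both HFD libraries than in both control libraries, where chance gives 16.7% per direction. Ifit3 (−4.01 ± 1.25), Irf7 (−2.09 ± 0.67), Oasl2 (−1.65 ± 0.62) and Ifit2 (−1.38 ± 0.48) led, and 12 of the 17 members stood under 10% of their highest class. Control 2 carried much of this: the median was −0.23 without it, and that of the MHC class I list named next was 0.15. Genes of MHC class I presentation fell as a list (−0.53, 0.000585); 0 of its 10 members passed, and 1, Nlrc5 (−1.12 ± 0.49), was lower in both HFD libraries than in both control libraries. NF-kB inflammation genes rose (0.58, 1.14e-09), with Cxcl1 (2.10 ± 0.53), Nfkb1 (0.58 ± 0.20) and Relb (0.59 ± 0.24) higher in both HFD libraries. HFD 1 carried much of the Cxcl1 fold, with a CPM of 41.6 against 12.5 in HFD 2 and 6.62 and 5.87 in the control libraries. Of the 19 members 12 stood under 10% of their highest class, Cxcl1 at 1.66%. Cholesterol synthesis genes rose (0.31, 8.56e-05), with Hmgcs1 at 0.53 ± 0.19, and 10 of their 21 members were higher in both HFD libraries. Androgen response genes (0.19, 0.0191), with Homer2 at 0.67 ± 0.21, and secretory protein genes (0.42, 0.0143) were higher as lists. Of the 20 androgen response members 14 were higher and 6 lower, with Tmprss2 at −0.463 ± 0.205. Wnt and Notch signalling genes rose (0.30, 0.00581), with Hes1 at 0.80 ± 0.22 and Notch2 at 0.66 ± 0.20, while Lgr5 was at −0.73 ± 0.26. Of the 15 members, 7 were higher and 3 lower in both HFD libraries than in both control libraries. Adjusted over the list alone, 0 members passed in any of these lists.

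Extracellular matrix genes (0.70, 1.16e-08), basement membrane genes (0.48, 0.00396) and insulin and IGF signalling genes (0.32, 0.000317) also rose in secretory luminal-like cells. Their leading members Acta2 (1.66 ± 0.25), Tnc (2.41 ± 0.72), Lama2 (0.54 ± 0.36) and Igfbp6 (2.60 ± 0.78) stood at 0.0535 to 0.29% of their level in the class where each was highest, and Acta2 was the 1 member that passed when adjusted over the list alone. Lists of the cell's own machinery moved less: ribosomal protein genes fell (−0.21, 2.47e-05), as did oxidative phosphorylation (−0.13, 0.0082), unfolded protein response (−0.23, 0.000723, but 0.06 without HFD 2) and immediate early genes (−0.14, 0.0352), and mitochondrially encoded RNA rose (0.19, 0.0282). Asns (−0.45 ± 0.22), Sdhb (−0.30 ± 0.21) and Fosb (−0.48 ± 0.21) were examples. Camera's adjusted p was between 0.70 and 0.757 for all 15 lists with an estimated correlation.

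Seminal vesicle epithelial-like cells, which secrete the bulk of seminal fluid, had lower NF-kB and respiratory gene lists and higher secretory and cholesterol synthesis lists with HFD; all were lost with an estimated correlation (camera adjusted p = 0.70 to 0.772), and the NF-kB list turned to 0.15 without control 2. Cluster 1 held 56.0% of these cells in control and 77.5% in HFD libraries and cluster 15 held 38.7% and 14.5%, and the class test sums them together. For cluster 1 the groups overlapped, with 263 of 366 cells in control 1 and 187 of 352 in HFD 2. Tested singly, clusters 1 and 15 had 0 genes past the edgeR test, with 276 and 107 at an unadjusted p below 0.05. Of 11515 genes, edgeR called 0 and gave 319 an unadjusted p below 0.05; DESeq2 called 2, Tcaf3 (1.56) and the haem oxygenase gene Hmox1 (−1.50), with an adjusted p of 0.0164 each. By edgeR, Hmox1 was −1.50 ± 0.26 and Tcaf3 1.57 ± 0.21, the latter at 1.41% of its highest class, and Ppp1r1b (−1.20 ± 0.22), Fam129a (−1.09 ± 0.20) and Fam3b (−0.97 ± 0.19) were lower in both HFD libraries. Fam3b was among the 10 leading genes of cluster 15, so its lower value cannot be told apart from that cluster's smaller part in HFD libraries. The edgeR adjusted p was 0.788 for Tcaf3 and 1.0 for the others.

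Of 25 lists in seminal vesicle epithelial-like cells, 12 passed, 6 in each direction, and 0 with an estimated correlation (adjusted p = 0.70 to 0.772). NF-kB inflammation genes fell (−0.22, camera adjusted p = 0.0352), with Tnfaip3 at −1.07 ± 0.33 and Nfkbia at −0.68 ± 0.34, and MHC class I genes fell (−0.35, 0.0181), with B2m at −0.53 ± 0.40 and overlapping groups; without control 2 the medians of these lists were 0.15 and 0.36. The NRF2 and oxidative stress list fell (−0.08, 0.0477), and Hmox1 was its 1 lower member adjusted over the list alone; without genes under 10% of their highest class its median was 0.007 and its direction turned (camera adjusted p = 0.879). Oxidative phosphorylation (−0.16, 0.00211), glycolysis (−0.17, 0.0443) and ribosomal protein genes (−0.14, 0.042) were lower, with Cox6c at −0.56 ± 0.24, Ldha at −0.41 ± 0.19 and Rps2 at −0.34 ± 0.25. Cholesterol synthesis genes rose (0.31, 0.0262), with Hmgcs1 at 0.55 ± 0.25, and mitochondrially encoded RNA rose (0.34, 0.00347). Prostate secretory protein genes rose (0.91, 4.29e-07): adjusted over the list alone, Tgm4 (0.99 ± 0.21) and Pbsn (0.98 ± 0.21) were higher, at 1.11 and 1.55% of their highest class, and Wfdc15b (−0.91 ± 0.23), highest in these cells, was lower. Wfdc15b was among the 10 leading genes of cluster 15, which held a smaller part of these cells in the HFD libraries. Its lower value cannot be told apart from that shift. Androgen response (0.20, 0.00219), insulin and IGF signalling (0.26, 0.0021) and matrix genes (1.1, 1.54e-07) were higher. Adjusted over the list alone, the matrix genes Acta2 (1.88 ± 0.26), Thbs1 (1.47 ± 0.41) and Fn1 (2.50 ± 0.79) were higher, at 0.0513 to 1.01% of their highest class. With genes under 10% of their highest class left out, 2 lists passed, 1 in each direction.

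Basal-like cells line the epithelium's base and renew it. Their cell cycle, cholesterol synthesis and glycolysis lists fell with HFD, while transcripts of prostate secretory proteins rose; all were lost with an estimated correlation (camera adjusted p = 0.70 to 0.757). Of 10833 genes, edgeR called 0 and gave 232 an unadjusted p below 0.05, and DESeq2 called 5, all higher, of which Pbsn, Tgm4 and 9530053A07Rik encode secretory proteins and 9530002B09Rik and Gm47283 were the others. Genes with a small edgeR p were Cdcp3 (1.59 ± 0.26), the stress gene Nupr1 (1.48 ± 0.25), Tcaf3 (1.44 ± 0.26), Pbsn (1.28 ± 0.23) and Msmb (1.32 ± 0.27), at 1.02 to 4.13% of their highest class, with edgeR adjusted p from 0.24 to 0.384. Without control 1, edgeR called 73 genes, without control 2 it called 63, without HFD 1 it called 2 and without HFD 2 it called 1.

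Of 25 lists in basal-like cells, 8 passed, 3 higher and 5 lower, and 0 with an estimated correlation (adjusted p = 0.70 to 0.757). Cell cycle genes had a median of −0.41 (camera adjusted p = 0.00193), with 17 of 18 members lower, among them Ube2c (−2.35 ± 0.65) and Rrm2 (−0.76 ± 0.30). Cholesterol synthesis genes fell (−0.26, 0.00179), with Insig1 at −0.61 ± 0.27 and Cyp51 at −0.56 ± 0.29. Glycolysis and hypoxia genes (−0.22, 0.0115), such as Egln3 (−0.48 ± 0.25), interferon response genes (−0.16, 0.042) and immediate early genes (−0.14, 0.0488), such as Dusp1 (−0.59 ± 0.22), also fell; the interferon list turned direction without control 2 (median 0.29) and the cell cycle list without HFD 2 (median −0.013, camera direction higher). Adjusted over the list alone, 0 members of these 5 lists passed. Prostate secretory protein genes rose (1.22, 2.86e-24), and 7 members were higher adjusted over the list alone, led by Pbsn, 9530053A07Rik (1.44 ± 0.27), Msmb and Tgm4 (1.22 ± 0.25). The list took 0.455% and 0.19% of the UMIs of basal-like cells in the control libraries and 0.955% and 0.563% in HFD 1 and HFD 2, against 10.6 to 23% in secretory luminal-like cells. Androgen response genes rose (0.19, 8.71e-05), with Pbsn and Msmb adjusted over the list alone, and mitochondrially encoded RNA rose (0.41, 1.39e-05). Pbsn and Msmb are members of the secretory list too and stood at 4.13 and 1.32% of their highest class. Of the 19 androgen response members tested, 8 stood under 10% of theirs.

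Fibroblast-like cells build the stroma and its matrix. Interferon response, matrix, basement membrane and Wnt and Notch genes fell as lists in them, and cholesterol synthesis and stress response lists rose. All were lost with an estimated correlation (camera adjusted p = 0.70 to 0.772), and the basement membrane and unfolded protein response lists turned direction without HFD 1. Of 7071 genes, edgeR called 0 and gave 145 an unadjusted p below 0.05; DESeq2 called 4, all higher, namely Svs6, Spinkl, Cxcl2 and 9530003J23Rik. The Wnt antagonist gene Sfrp4 was −4.88 ± 0.76, with a CPM of 77.3 and 53.6 in the control libraries and 0 and 3.13 in the HFD libraries, and the retinol carrier gene Rbp4 was −2.57 ± 0.47; neither passed (edgeR adjusted p = 0.999 for each). Svs6 (4.38 ± 0.76) and Spinkl (3.88 ± 0.77) stood at 2.89 and 3.53% of their highest class, and Frk (2.04 ± 0.41) at 16.3%. In simulated data of the same libraries, changes of 2 log2 units were recovered for 44% of the changed genes in this class and for 96 to 100% in the other main classes. These genes had a mean log2 CPM of at least 4 and the spread typical for their level. Recovery of genes with fewer counts or a larger spread between libraries was not simulated. Without HFD 2, edgeR called 203 genes in this class, and without HFD 1 it called 6.

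Of 23 lists in fibroblast-like cells, 10 passed, 6 higher and 4 lower, and 0 with an estimated correlation (adjusted p = 0.70 to 0.772); 0 members of these lists passed when adjusted over the list alone. Interferon response genes fell (−0.69, camera adjusted p = 1.54e-06), with Ifit1 (−2.09 ± 0.56), Ifit3 (−2.46 ± 0.84) and Irf7 (−1.19 ± 0.48) lower in both HFD libraries. Matrix genes fell (−0.54, 0.000339), with Timp1 (−1.39 ± 0.40), the elastin gene Eln (−1.53 ± 0.66) and Col3a1 (−0.89 ± 0.46) lower in both, as did basement membrane genes (−0.50, 0.0106), with Col4a2 at −0.68 ± 0.43. Wnt and Notch signalling genes fell (−0.60, 0.0357), with Wnt10a at −1.77 ± 0.75 and Wnt5a at −0.81 ± 0.47. Cholesterol synthesis genes rose (0.43, 0.000877), with Msmo1 at 1.80 ± 0.64 and Idi1 at 1.74 ± 0.64, and all 7 tested members were higher. The NRF2 list (0.47, 0.00322), with G6pdx at 1.46 ± 0.57, the unfolded protein response (0.44, 0.0181), with Ddit3 at 0.92 ± 0.40, and mitochondrially encoded RNA (0.64, 0.00141) rose. Epithelial transcripts rose too: prostate secretory proteins (1.23, 0.000585), with Tgm4 at 1.82 ± 0.65, and the proximal luminal programme (0.69, 0.0145), with Clu at 4.52 ± 1.51 and Krt19 at 2.21 ± 0.81. HFD 1 carried these folds: Clu had a CPM of 5936 in HFD 1 and 155.0 in HFD 2, and without HFD 1 the log2 fold changes were 0.72 for Tgm4, 0.23 for Clu and 0.47 for Krt19. Without HFD 1 the basement membrane, proximal luminal and unfolded protein response lists turned direction while 4 lists passed in all.

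**Figure D2:**
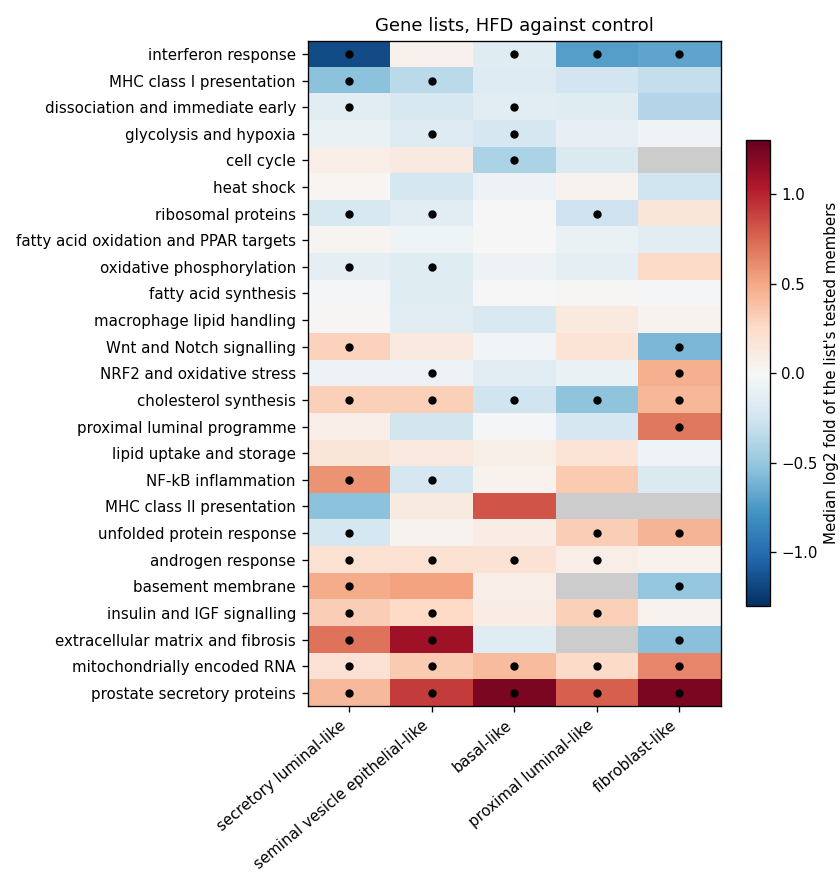
Median log2 fold change of HFD over control for 25 gene lists in the 5 main classes, with a dot where limma camera's adjusted p is below 0.05 and grey where fewer than 5 members were tested. Interferon response is lowest in secretory luminal-like cells (−1.16), and prostate secretory proteins are highest in fibroblast-like (1.23) and basal-like cells (1.22); with an estimated correlation 0 lists pass.

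By the preset correlation, interferon response genes were lower in 4 of the 5 main classes; with an estimated correlation the adjusted p was 0.70 to 0.757, and without control 2 the median was 0.29 in basal-like and −0.05 in proximal luminal-like cells. Irf7, a master switch of the type I interferon response, was lower in both HFD libraries than in both control libraries in each of these 4 classes. Irf7 (ENSMUSG00000025498.15; mm10 chromosome 7, 141262706 to 141266481, minus strand) had a CPM of 20.3 and 85.2 in the control libraries against 16.7 and 8.28 in the HFD libraries in secretory luminal-like cells. In proximal luminal-like cells it was 68.5 and 99.9 against 27.4 and 30.5. In basal-like cells its log2 fold change was −0.75 ± 0.30. Without control 2 it was −0.73 in secretory luminal-like, −0.42 in basal-like, −1.24 in proximal luminal-like and −0.88 in fibroblast-like cells. It did not pass over all genes in any class (edgeR adjusted p = 0.795 in proximal luminal-like, 0.999 in fibroblast-like and 1.0 in the other cells). In seminal vesicle epithelial-like cells the interferon list had a median of 0.06, a mean of −0.03 and a lower direction in the test (camera adjusted p = 0.466). Median, mean and test had the same sign for all 53 lists that passed and differed for 16 of the 67 that did not.

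**Figure D3:**
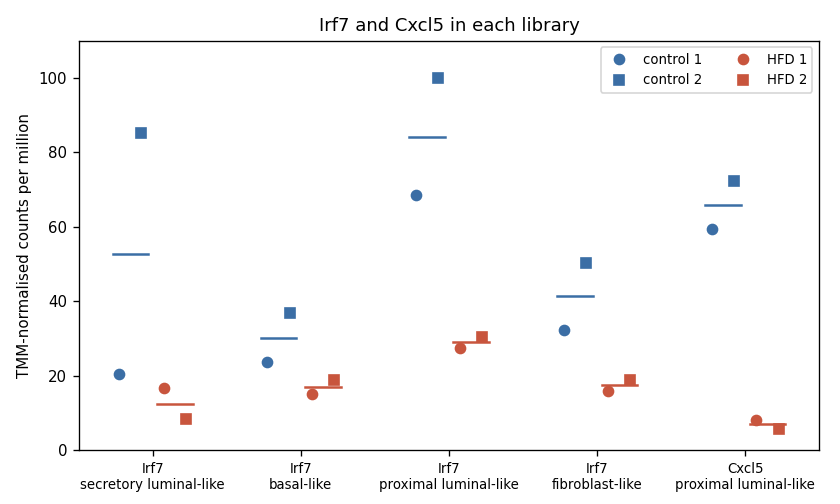
TMM-normalised CPM of Irf7 in 4 classes and of Cxcl5 in proximal luminal-like cells, with 1 point per library and a line at each group's mean. Cxcl5 is at 59.3 and 72.4 in the control libraries and at 8.05 and 5.81 in the HFD libraries.

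Lists of lipid use other than cholesterol synthesis did not pass in any main class. Fatty acid synthesis genes had medians from −0.16 to 0.02 and a smallest camera adjusted p of 0.648. Fatty acid oxidation genes had medians from −0.15 to 0.04 (smallest 0.343), lipid uptake and storage genes from −0.06 to 0.18 (smallest 0.199), and macrophage lipid handling genes a smallest adjusted p of 0.0736, in basal-like cells. Heat shock genes did not pass either (smallest camera adjusted p = 0.09). MHC class II genes had enough members in secretory luminal-like, seminal vesicle epithelial-like and basal-like cells only, and did not pass there (smallest 0.0531).

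Smooth muscle-like cells, the contractile layer around the glands, had the largest count of genes past the edgeR test among the other classes. Cluster 36 held 8.14% of these cells in control and 25.3% in HFD libraries, and the rest were cluster 13. Of the HFD cells of cluster 36, 12 were in HFD 1 and 105 in HFD 2. Of 7989 genes, edgeR called 23, of which 21 were higher and 2 lower, and DESeq2 called 35. The developmental transcription factor gene Osr1 fell by 2.74 ± 0.37 on the log2 scale (CPM 53.5 and 56.5 in the control, 8.58 and 7.97 in the HFD libraries, edgeR adjusted p = 0.0204), and Wnt2 fell by 2.52 ± 0.41 (edgeR adjusted p = 0.0468). Neither was called with doublets kept or with equal cell numbers, and Wnt2 was not called without genes under 10% of their highest class. The higher genes included Svs6 (4.38 ± 0.65), Sprr1a (3.80 ± 0.34), Krt19 (3.33 ± 0.36), Svs4 (3.29 ± 0.34) and Agr2 (3.25 ± 0.40), epithelial genes that stood at 2.32 to 9.84% of their highest class. With doublets kept edgeR called 0 genes here, with equal cell numbers 4, without genes under 10% of their highest class 5, and without 1 library between 47 (HFD 2) and 188 (control 1). In mononuclear phagocyte-like, pericyte-like, endothelial-like, urothelial-like and ionocyte-like cells edgeR called 0 genes, with 229, 63, 163, 507 and 215 at an unadjusted p below 0.05. DESeq2 called 0, 0, 0, 38 and 1 in this order. Among these classes only urothelial-like cells, with 507 of 6877 genes, had more at that limit than chance alone would give. Smooth muscle-like cells did so too, with 547 of 7989.

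The effect of HFD was compared directly between secretory luminal-like and fibroblast-like cells of the same libraries. Of 14707 genes, 0 had a different effect by edgeR's interaction test. At an unadjusted p below 0.05 there were 487, fewer than chance alone would give. The desmin gene Des was first (edgeR adjusted p = 0.61). Without HFD 2 the count was 697, without HFD 1 it was 30, without control 1 it was 10 and without control 2 it was 2.

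Cells with UMIs of proliferation genes were counted with all cells at 1 depth. With each cell thinned to 1000 UMIs, cells with at least 2 UMIs of 6 proliferation genes were 0.929% ± 1.13 of secretory luminal-like cells in control and 0.561% ± 0.199 in HFD libraries (exact permutation p = 1.0). In control 1 these were 1 of 777 cells and in control 2 16 of 926; 9, 40, 0 and 18 shallower cells of control 1, control 2, HFD 1 and HFD 2 were left out. Without thinning, 10.6% and 8.7% of secretory luminal-like cells in the control and 4.63% and 5.47% in the HFD libraries had such UMIs, at unequal depth. Basal-like cells held 0.0855% ± 0.121 in control and 0 in HFD libraries. There 0 of 216 and 0 of 702 cells allow up to 1.39% and 0.427% of cells with such UMIs at this depth, which does not limit dividing cells: without thinning 3.7% and 0.141% had them. Seminal vesicle epithelial-like cells held 0.278% ± 0.393 and 0, fibroblast-like cells 0 and 0.705% ± 0.997 (1 of 71 cells of HFD 1), and proximal luminal-like cells 0 in both groups (exact permutation p = 1.0 for each).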

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

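The list tests of the difference between classes were chosen after the data were seen, as were all tests of explanations here except the one of doublets with secretory cells. Each result named in the next 2 paragraphs stands out because the HFD effect on a gene list differed between secretory luminal-like cells and another main class by a test of the difference itself. Of 100 combinations of list and class 27 passed, and all are named. A difference is the median over the genes tested in both classes together, so it need not equal the gap between the classes' own medians. With an estimated correlation 0 passed: the adjusted p was 0.951 for the interferon genes of seminal vesicle epithelial-like and the ribosomal protein genes of basal-like cells, and 0.856 for each of the others.

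NF-kB inflammation genes had a median log2 fold change of 0.58 in secretory luminal-like and −0.22 in seminal vesicle epithelial-like cells, with a difference between the effects of −0.77 (camera adjusted p = 8.01e-06). Of the list's 19 members tested in secretory luminal-like cells 12 stood under 10% of their highest class, Cxcl1 at 1.66%. The difference was −0.30 in basal-like (0.00793) and −0.26 in proximal luminal-like cells (0.00197). Cholesterol synthesis genes moved in opposite directions in secretory luminal-like cells (0.31) and in the less differentiated epithelium, with differences of −0.69 for basal-like (1e-07) and −0.94 for proximal luminal-like cells (1.19e-05), and differed by 0.25 in fibroblast-like cells (0.0496). The unfolded protein response, which tracks the load of protein folding, differed by 0.38 in seminal vesicle epithelial-like (0.000832), 0.37 in basal-like (0.000135), 0.48 in proximal luminal-like (5.42e-06) and 0.69 in fibroblast-like cells (2.21e-05). Single HFD libraries carried much of this. The list's own median was 0.06 in secretory luminal-like cells without HFD 2. Without HFD 1 it was 0.02 in proximal luminal-like and −0.31 in fibroblast-like cells.

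Interferon response genes differed by 1.15 in seminal vesicle epithelial-like (0.0111) and 1.21 in basal-like cells (9.71e-06), where their own medians were 0.06 and −0.16. Cell cycle genes differed by −0.53 in seminal vesicle epithelial-like (5.13e-05) and −0.72 in basal-like cells (0.000383), and the proximal luminal programme by −0.45 in the former (0.00162). The classes' own cell cycle medians were 0.09 in secretory luminal-like, 0.11 in seminal vesicle epithelial-like and −0.41 in basal-like cells. In seminal vesicle epithelial-like cells, 12 of the 15 cell cycle members tested in that class alone stood under 10% of their highest class. Basal-like cells differed further by 0.66 for prostate secretory proteins (1.75e-05), 1.42 for MHC class II (0.0118), −0.81 for extracellular matrix (0.000708), 0.21 for mitochondrially encoded RNA (0.0117) and 0.21 for ribosomal protein genes (0.0112). All 7 MHC class II members tested stood under 10% of their highest class in basal-like and in secretory luminal-like cells. The MHC class II list itself passed in neither class. Fibroblast-like cells differed further by −1.21 for extracellular matrix (1.44e-05), −0.99 for basement membrane (0.00109) and −0.57 for Wnt and Notch signalling genes (0.0054). Their energy, stress and ribosomal lists differed by 0.34 for oxidative phosphorylation (0.00075), 0.42 for mitochondrially encoded RNA (0.00214), 0.36 for NRF2 and oxidative stress (0.00178) and 0.34 for ribosomal protein genes (0.000246). In secretory luminal-like cells 13 of the 14 tested matrix genes stood under 10% of their highest class, Acta2 at 0.0684%, so for the matrix lists free RNA of stromal cells stays open. No explanation was tested for the differences of the other lists between classes.

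Lymphocyte-like cells were fewer in the HFD libraries. The tables argue against the higher UMI minimum of HFD 1 as the whole cause: with 1 minimum in all libraries the log2 fold changes were −3.84 for B or plasma cell-like and −3.44 for T or NK cell-like cells (edgeR adjusted p = 0.00329 for each). Lymphoid tissue in the control libraries alone, such as a lymph node taken along in dissection, stays open as a possible explanation: 34 control cells and 0 HFD cells held a UMI of Glycam1, a gene of the venules through which lymphocytes enter lymph nodes. Of these 28 were in control 1 and 6 in control 2, although control 2 held more B or plasma cell-like and T or NK cell-like cells. The 95% interval of control 2 (0.143%, 0.0525 to 0.311%) reaches the upper limits of HFD 1 (0.0774%) and HFD 2 (0.0649%). Overlap of intervals is not a test of a difference, and no such test was run, so the intervals decide nothing for control 2. The Glycam1-led cluster 31 had a median of 1034 UMIs, while HFD 1 held no barcode under 2891 UMIs. The 0 cells of HFD 1 therefore say little here. A loss of lymphocytes from the prostate through the diet stays open and was not tested apart from this.

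Interferon response genes were lower with HFD in 4 main classes by camera's preset correlation, with an adjusted p of 0.757 in basal-like cells and 0.70 in each of the others with an estimated correlation. That 1 control library with high interferon genes explains it stays open: control 1 lay above both HFD libraries for over 50% of the members in 1 of 4 classes, with 29.4% of members in secretory luminal-like, 20% in basal-like, 46.7% in proximal luminal-like and 58.3% in fibroblast-like cells, where chance gives 33.3%. For control 2 these were 94.1%, 60%, 80% and 75%. Without control 2 the medians were −0.23 in secretory luminal-like (camera adjusted p = 0.036), 0.29 in basal-like (0.174), −0.05 in proximal luminal-like (0.0425) and −0.50 in fibroblast-like cells (0.00384). Free RNA of other cells was examined by leaving out genes under 10% of their highest class. In proximal luminal-like cells 9 of the 15 members remained, with a median of −0.70 (camera adjusted p = 9.54e-06, preset correlation). For these 9 members this argues against free RNA as the whole cause. The filter took out Ifi27l2a, Ifi44 and Ifit3, and it cannot exclude free RNA in the genes it keeps. In fibroblast-like cells this filter removed none of the 12 members (−0.68, 2.84e-06) and decides nothing. Free RNA could not be excluded either in secretory luminal-like cells, where the median went from −1.16 to −0.46 (1.76e-05), or in basal-like cells (−0.18, 0.092). An effect of the diet on interferon signalling may add to these and cannot be told apart from a control library with an infection or another stimulus.

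Prostate secretory transcripts were higher with HFD in classes other than secretory luminal-like cells. Free RNA from secretory cells stays open: the median log2 difference was above 0 in 10 of the 10 classes tested outside secretory luminal-like cells, immune and stromal classes included, but the list's share of UMIs lay above both control libraries in both HFD libraries in 4 of them. It was lower in HFD 2 than in control 1 in fibroblast-like (0.795% and 1.73%) and endothelial-like cells (0.68% and 3.1%). Tgm4 took 0.322% of the UMIs of HFD 1 and 0.567% and 0.638% of those of the control libraries, yet its CPM in basal-like cells was 789 in HFD 1 and 312.5 and 258.2 in the control libraries. Doublets with secretory cells could not be told apart from free RNA: the median basal-like cell held 0.442% and 0.169% of its UMIs from this list in the control and 0.487% and 0.591% in the HFD libraries, so the lower HFD library lay at 1.1 times the higher control library. In fibroblast-like cells of HFD 1 the mean cell held 6.59% and the median cell 0.417%, so few cells carried most of it there. A change of the basal-like cells themselves stays open as a biological explanation, untested.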

How the results depend on the processing

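The common UMI minimum, and leaving out libraries for the interaction and for dividing cells, were alternatives chosen after the data were seen; the cause of a change was not tested unless the setting's own construction gives it. When a library is left out, the lone library of its group is assumed to vary like the other group. Counts of genes past the edgeR threshold, in the order secretory luminal-like, seminal vesicle epithelial-like, basal-like, proximal luminal-like and fibroblast-like cells, were 0, 0, 0, 1 and 0; with DESeq2 they were 12, 2, 5, 2 and 4, and with no low-count filter 111, 85, 55, 68 and 95. Without 1 library they ranged from 1 to 17 (secretory luminal-like), 1 to 73 (basal-like), 10 to 35 (proximal luminal-like) and 0 to 203 (fibroblast-like), and were 0 each time in seminal vesicle epithelial-like cells. Naming by marker score gave 1 in secretory luminal-like cells (Wfdc2) and Svs6 in place of Cxcl5 in proximal luminal-like cells, and doublets kept and equal cell numbers gave 0 in proximal luminal-like cells. RLE size factors and the limits on genes and mitochondrial UMIs left these counts as they were. Lists past the threshold went from 15, 12, 8, 8 and 10 to 0, 0, 0, 0 and 0 with an estimated correlation and with fry; fry has no comparison with other genes. With genes under 10% of their highest class left out, so with fewer genes, 9, 2 and 5 lists passed in secretory luminal-like, seminal vesicle epithelial-like and basal-like cells. Without 1 library, 4 to 12 lists passed in fibroblast-like cells. Class shares went from 1 past the threshold to 2 with naming by marker score, 2 with the common UMI minimum, 0 within epithelial or non-epithelial cells and 3 with both, and to between 0 and 1 without 1 library, which leaves fewer samples. Epithelial cluster shares stayed at 0 at each resolution and without each library. Genes with a different effect between classes went from 0 to 45 with no low-count filter and to between 2 and 697 without 1 library. Dividing cells (HFD minus control, in percentage points) went from −0.368 to −4.6 in secretory luminal-like, −0.0855 to 0.347 in basal-like, 0 to 0.469 in proximal luminal-like and 0.705 to 1.91 in fibroblast-like cells with no thinning, where depth enters. With at least 1 UMI they were −0.905 in secretory luminal-like, 0.509 in seminal vesicle epithelial-like, −0.65 in basal-like, −0.0735 in proximal luminal-like and 0.558 in fibroblast-like cells. Without 1 library they ranged from −1.17 to 0.432 (secretory luminal-like), −0.556 to 0 (seminal vesicle epithelial-like), −0.171 to 0 (basal-like) and 0 to 1.41 (fibroblast-like). Among the 53 list results, medians turned or the test's direction turned without 1 library, with these ranges: in basal-like cells, cell cycle −1.03 to −0.013 and interferon −0.643 to 0.289; in fibroblast-like cells, basement membrane −1.54 to 0.093, proximal luminal programme −0.43 to 3.67 and unfolded protein response −0.309 to 0.864; in proximal luminal-like cells, unfolded protein response 0.023 to 0.519; in secretory luminal-like cells, MHC class I −1.02 to 0.151 and unfolded protein response −0.73 to 0.063. In seminal vesicle epithelial-like cells these were MHC class I −1.13 to 0.359 and NF-kB −0.553 to 0.149, and the NRF2 list was at 0.007 with genes under 10% of their highest class left out. Of the other list comparisons without 1 library, 123 kept direction and call and 78 kept direction only; of those with other settings, 176 and 131. Among 226 results for genes of the 5 main classes, 2077 comparisons with other settings kept direction and side of the threshold. Only Cxcl5 had passed in the main setting, so for every other gene this means that it stayed short of the threshold. Of the remaining comparisons with other settings, 57 passed it newly in the same direction and 3 no longer did, all of Cxcl5. Calls in smooth muscle-like cells are not among these. Genes that turned direction without 1 library, with their ranges, were Msmb (−0.15 to 1.33), H2-T23 (−1.28 to 0.17), H2-K1 (−1.06 to 0.05), Tap1 (−1.15 to 0.13), Creld2 (−1.55 to 0.02), Atp5j2 (−0.58 to 0), Atp5e (−0.67 to 0.11) and Igfbp5 (−0.05 to 0.87) in secretory luminal-like cells, the last also with doublets kept (−0.09). In seminal vesicle epithelial-like cells they were H2-T23 (−1.57 to 0.12), Tap2 (−1.42 to 0.23), H2-K1 (−1.11 to 0.54), Ndufa1 (−1.07 to 0.14), Atp5e (−0.81 to 0.06) and Rpl37 (−0.78 to 0.26). In basal-like cells Fos did so (−0.56 to 0.05), and in proximal luminal-like cells mt-Nd2 (−0.05 to 0.72), mt-Co3 (−0.14 to 0.81), Igf1r (−0.03 to 1.09), Insr (−0.13 to 0.67) and Rpl37 (−0.80 to 0.09). In fibroblast-like cells Wfdc15b (−1.39 to 5.16), Sbp (−0.61 to 5.81), Herpud1 (−0.22 to 1.52), Wnt4 (−2.20 to 0.30) and Sox9 (−0.51 to 1.80) did so. Naming by marker score turned Ptgs2 (0.28) and Srxn1 (0.37) in seminal vesicle epithelial-like and Fdps (0.64) in proximal luminal-like cells. A gene or list with too few counts under a setting has no value there. Depth limits the shares of rare classes and of dividing cells, where 1 cell moves a value.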

Other observations

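The Glycam1, immunoglobulin and acute phase values here were looked at after the data were seen. The few B or plasma cell-like cells of the HFD libraries are set here beside those of the control libraries. Thinned to 1000 UMIs, naive B cell transcripts were seen in the control cells: Ighd in 12 of 49 B or plasma cell-like cells of control 1 and 50 of 171 of control 2, and the lymph node homing receptor Ccr7 in 22 and 79 of them. In HFD 1 and HFD 2 Ighd was seen in 0 of 3 and 2 of 10 cells and Ccr7 in 0 and 1. The plasma cell gene Jchain was seen in 3 of 3 and 7 of 10 HFD cells and in 1 of 49 and 9 of 171 control cells, and Igha in 3 and 5 HFD cells and in 0 control cells. The background in fibroblast-like cells thinned alike was 0 of 159, 134, 71 and 185 cells for Ighd and for Ccr7, 0, 0, 0 and 3 for Jchain and 1, 0, 0 and 1 for Igha, from median depths of 5227, 3005, 4975 and 2991 UMIs against 3361, 1914, 3967 and 3400 in B or plasma cell-like cells. With so few cells in the HFD libraries these are values without a test. Among T or NK cell-like cells, Ccr7 was seen in 13.6% and 15.3% of control and 0% and 2.04% of HFD cells, and the effector chemokine gene Ccl5 in 31.2% and 58.2% of control and 40% and 65.3% of HFD cells, of 154, 411, 5 and 98 cells; Ccl5 was seen in 0, 0, 0 and 1 of the fibroblast-like cells.

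Of the 9 clusters left unnamed because over 90% of their cells came from 1 library, 31 and 37 came almost wholly from control 1. The others came from HFD libraries: clusters 21 (351 of 364 cells) and 40 from HFD 1. Clusters 6 (582 of 613 cells), 26, 29, 30 and 38 came from HFD 2. Secretory luminal markers ranked first in clusters 21, 26, 29 and 30, whose cells are outside that class's share and gene tests. Cluster 31, led by Glycam1 with the vessel genes Selp, Vwf and Plvap, held 181 cells, 174 of them from control 1, at a median of 1034 UMIs. Cluster 37, led by the acute phase genes Saa3, Saa1 and Lcn2, held 131 cells, all from control 1. In urothelial-like cells, the lining of the urethra, DESeq2 called 38 genes, 23 higher and 15 lower, where edgeR called 0 of 6877. The genes of dissected epithelium differed by library: Msmb took 0.269% and 0.228% of the UMIs of the control and 0.5% and 0.246% of those of the HFD libraries, Pbsn 0.656%, 0.763%, 0.593% and 0.898%, Sbp 2.18%, 1.14%, 3.06% and 2.01%, Spink1 2.07%, 0.513%, 2.52% and 1.53%, and Tgm4 0.567%, 0.638%, 0.322% and 0.662%, in the order control 1, control 2, HFD 1 and HFD 2.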
